A study of Ovis aries with 72 samples.

How the data were processed

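The series holds globin-depleted RNA from the blood of Sarda sheep, read on one-colour oligonucleotide arrays after 2 rounds of amplification and labelling with Cy5. Per the labels, equal amounts of RNA from each sheep of a group were combined at each time, which gave 18 pools from 6 groups and 3 times, and each pool was hybridised in duplicate on 36 slides. The deposited samples number 72 because every array is listed once for each of its 2 probe sets. The paired listings of an array held identical contents and were used once. The pool was taken as the sample, since duplicate hybridizations of a pool are technical repeats.

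The deposited scanner output gives intensity per spot, as a mean and a median over pixels, with no normalisation and no separate background column. How the background was treated is not given in the sources used here. Blank spots had a median of 1 on most arrays, the lowest value of the scale, with 6 arrays above it and a highest median of 138, so no further background was subtracted. The authors' processed matrix holds intensity on a linear scale, with column medians from 887 to 1695, and the steps behind it are not given in the sources used here. Of its 72 columns, 31 matched best the array they are listed under, and 40 matched best the duplicate array of the same pool. The 1 other column, for replicate 1 of the ACTH group at 0 with probe set 2, matched best Ctr at 0, at a correlation of 0.699. The matrix was therefore used as an alternative only.

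Each array carried 94928 spots, of which 4398 were controls or blanks, and 24384 probes for 12193 targets. Of the targets, 12191 had 2 probes, and a probe was spotted 3 to 6 times. The median pixel intensity was averaged over the spots of a probe, an offset of 50 was added, and the values were log2 transformed and quantile normalised over the 36 arrays. The probes of a target were then averaged. A target was kept where it lay above the 95th percentile of the 315 negative control spots on both arrays of at least 1 pool, which left 9714 targets. A gene description was given for 868 targets, of which 744 were kept. The other 11325 targets are expressed sequences without a description and enter the counts without being named. From the descriptions, 126 symbols were assigned to 212 targets, and 104 of these symbols occur in the sheep gene table. No genome position is given for a target, and none was used here.

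The main comparisons used 1 limma fit over the 18 pools, with the mean of the duplicate hybridizations as the value of a pool. The fit held 10 coefficients for group, for time in the injected groups and for the change of Ctr, taken as uninjected at all 3 times, and left 8 residual degrees of freedom, to which empirical Bayes added a prior of 5.62. Tests were two-sided, and p values were adjusted by the Benjamini-Hochberg method over the 9714 targets at a threshold of 0.05. Errors given after ± are standard errors from the fit. A second limma fit over the 36 arrays, with 18 pool means and 18 residual degrees of freedom, compared single RNA pools against the spread between duplicate hybridizations. It tests whether pools differ and never whether conditions differ.

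Fixed gene lists were tested in the pool fit with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, where at least 5 members were kept. The tested lists were neutrophil markers, T cell markers, monocyte and dendritic cell markers, inflammatory cytokines, Toll-like receptor signalling, antigen presentation, the glucocorticoid receptor axis, adhesion and ribosomal proteins. Lists with too few members for a test were glucocorticoid-induced genes, B cell, natural killer cell, erythroid and platelet markers, interferon response, antioxidant, heat shock, circadian clock, immediate early, apoptosis, cell cycle and oxidative phosphorylation genes. List medians were also set against 10000 random lists matched on signal.

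The groups, comparisons, lists, the main alternatives and the rule for named genes were fixed before the data were examined. For the changes with time the rule took up to 10 described targets with the largest rise and 10 with the largest fall among those past the threshold with 1 direction in all 5 injected groups. For the diet comparisons it took the 5 largest each way with 1 direction at all 3 times, and for the single pools the 5 largest each way in which both hybridizations of each pool lay on 1 side. List members past the threshold were added, and where fewer than 5 targets passed, the 5 described targets with the smallest p were given as values. Alternatives changed the scaling between arrays, the background, the filter, the probe set, the source of the values and the treatment of duplicate arrays, or left out a hybridization, a group or a time. The mean pixel column, cyclic loess, leaving out 2 doubted arrays of the Echi group, leaving out replicate 1 of the ACTH group at 0 and leaving out each array in turn in the pool fit were added after the data were seen. The replicate numbers of the arrays do not pair: the difference between replicates 1 and 2 correlated between pools from -0.832 to 0.746, with a median of 0.0167.

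The pool fit was tested on simulated data with 200 changed targets. For the change from 0 to 51 it recovered 73.1% of changes of 0.5 on the log2 scale and 97.0% of changes of 1. For the injected groups against the control it recovered none of the changes of 0.5 and 34.3% of those of 1. The simulated pools had independent noise and no deviant array, so recovery in the real data may be lower. Software was R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and Python 3.11.15 with matplotlib 3.10.9.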

Results

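Gene expression was measured in blood of Sarda sheep from 6 groups sampled at 3 times. The ACTH group received the basal diet and an injection of adrenocorticotropic hormone (ACTH), the pituitary hormone that drives cortisol release. Another 4 injected groups received a plant product: Andro received Andrographis paniculata, Echi received flowers of Echinacea angustifolia, Poli received roots of the same plant, and Larch received sawdust of Larix decidua. The control group, Ctr, received the basal diet; its labels give no treatment at times 3 and 51 but state an ACTH injection at time 0, a conflict that the labels leave open. Ctr was taken as uninjected at all 3 times, an assumption that its name and its labels at 3 and 51 support and its label at 0 contradicts. The times are the numbers 0, 3 and 51 without a unit. Each group and time was 1 RNA pool on 2 arrays, so 18 pools were compared, and the number of arrays limits the precision. The median intensity of an array lay between 804 and 2060, and between 64.4% and 84.3% of the targets exceeded the negative controls. Duplicate arrays of a pool correlated at 0.865 to 0.989 (median 0.959), and arrays of different pools at 0.745 to 0.992 (median 0.933). For 31 of 36 arrays the closest array came from another pool, with 34 such arrays to choose from against 1 duplicate. Replicate 1 of the ACTH group at 0 had the largest share of targets above the negative controls, 84.3%, and correlated with its duplicate at 0.902. Values without this array, an alternative chosen after the data were seen, are given below. The ACTH arrays at 3 and 51 had shares of 75.5% to 77.5% and replicate 2 at 0 had 65.2%, against a median of 71.4% over all arrays. An array of Echi reached 80.3%. Whether this bears on the comparisons with the ACTH group was not tested.

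The first comparison asked what changed from 0 to 3 in sheep given ACTH. NRAMP1 (U70255), the metal transporter of the macrophage phagosome also known as SLC11A1, rose by 0.87 ± 0.13 on the log2 scale (1.82-fold, n = 5 pools per time, limma adjusted p = 0.0155). Its level was higher in all 5 injected groups, from 0.36 in Poli to 1.13 in Echi, while the change in Ctr was -0.04. A transcript described as signal processing protein (AY392761) rose by 0.55 ± 0.09 (adjusted p = 0.0375), with -0.20 in Ctr. With replicate 1 of the ACTH group at 0 left out it had 0.62 ± 0.12 and the call was lost (adjusted p = 0.124), while NRAMP1 had an adjusted p = 0.0305. CD14, the monocyte coreceptor for lipopolysaccharide, had a value of 0.48 ± 0.10 that missed the threshold (adjusted p = 0.197). The monocyte and dendritic cell list, with CD14, CD80, MAFB, CD1B and CTSD as its 5 members, lay higher with camera (adjusted p = 0.0303, median 0.10). With an estimated correlation the unadjusted p = 0.0173 and the adjusted p = 0.156, so this call was lost after adjustment. No member passed over all targets with limma, and 1, CD14, passed when adjusted over the list alone. The same gene was the 1 member of the Toll-like receptor list (9 members) that passed when adjusted over the list alone.

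Across the array 9 targets rose and 1 fell from 0 to 3, of 9714 tested, with 300 at an unadjusted p under 0.05. The count was 1 without replicate 1 of every pool, 3 without the ACTH group, 6 without Andro, 1 without Echi and 2 without Larch. Among single arrays, it was 4 without replicate 1 of Andro at 0, and 6 without replicate 2 of Larch at 3 or of Poli at 51. Neutrophil markers (7, median 0.04), T cell markers (61, -0.02), inflammatory cytokines (19, 0.00), antigen presentation (33, 0.04), the glucocorticoid receptor axis (11, -0.03), adhesion (8, 0.02) and ribosomal proteins (10, 0.09) had no member past the threshold with limma, over all targets or adjusted over the list alone, and no call with camera or fry.

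The second comparison asked what differed at 51, the latest time, from 0. NRAMP1 stood higher again, by 1.02 ± 0.13 (adjusted p = 0.00208), in all 5 injected groups, against -0.15 in Ctr. Alpha-1 antitrypsin, an acute phase protease inhibitor, rose by 0.55 ± 0.12 (adjusted p = 0.0499), against -0.17 in Ctr. ISG15 (AF152103), the ubiquitin-like protein induced by interferon, fell by 1.83 ± 0.19 (adjusted p = 0.000597), with -1.36 in Ctr. Its change ran from -1.26 in Larch to -2.64 in Poli.

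Single described genes also fell at 51. CCR3 (AF266468), the eotaxin receptor of eosinophils and basophils, fell by 0.84 ± 0.13 (adjusted p = 0.00876) and its value in Ctr was also -0.84. Mast cell proteinase-3 fell by 0.62 ± 0.09 (adjusted p = 0.00832) and mast cell proteinase-1 fell by 0.39 ± 0.08 (adjusted p = 0.0499), with -0.06 and 0.11 in Ctr. GATA3, the transcription factor of T helper type 2 and innate lymphoid cells, fell by 0.98 ± 0.19 (adjusted p = 0.0382; Ctr -0.56). A clone of T19, the scavenger receptor family of gamma delta T cells, fell by 0.45 ± 0.09 (adjusted p = 0.0443), with -0.63 in Ctr. With probe set 1 alone the change of this clone was reversed. GATA3 and this clone were the 2 of 61 T cell list members past the threshold, and 7 fell when adjusted over the list alone, while the list median was -0.03. Tubulin-alpha fell by 0.89 ± 0.19 (adjusted p = 0.0499; Ctr -1.13). With replicate 1 of the ACTH group at 0 left out, the calls of NRAMP1 (adjusted p = 0.00525), ISG15 (0.00149) and mast cell proteinase-3 (0.0129) held. Those of CCR3 (-0.78 ± 0.15, adjusted p = 0.0716), mast cell proteinase-1 (-0.46 ± 0.09, 0.0716), GATA3 (-0.99 ± 0.19, 0.0684), the T19 clone (-0.45 ± 0.10, 0.0865), tubulin-alpha (-0.78 ± 0.22, 0.207) and alpha-1 antitrypsin (0.51 ± 0.13, 0.166) were lost, with the sign of each kept.

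**Figure D1:**
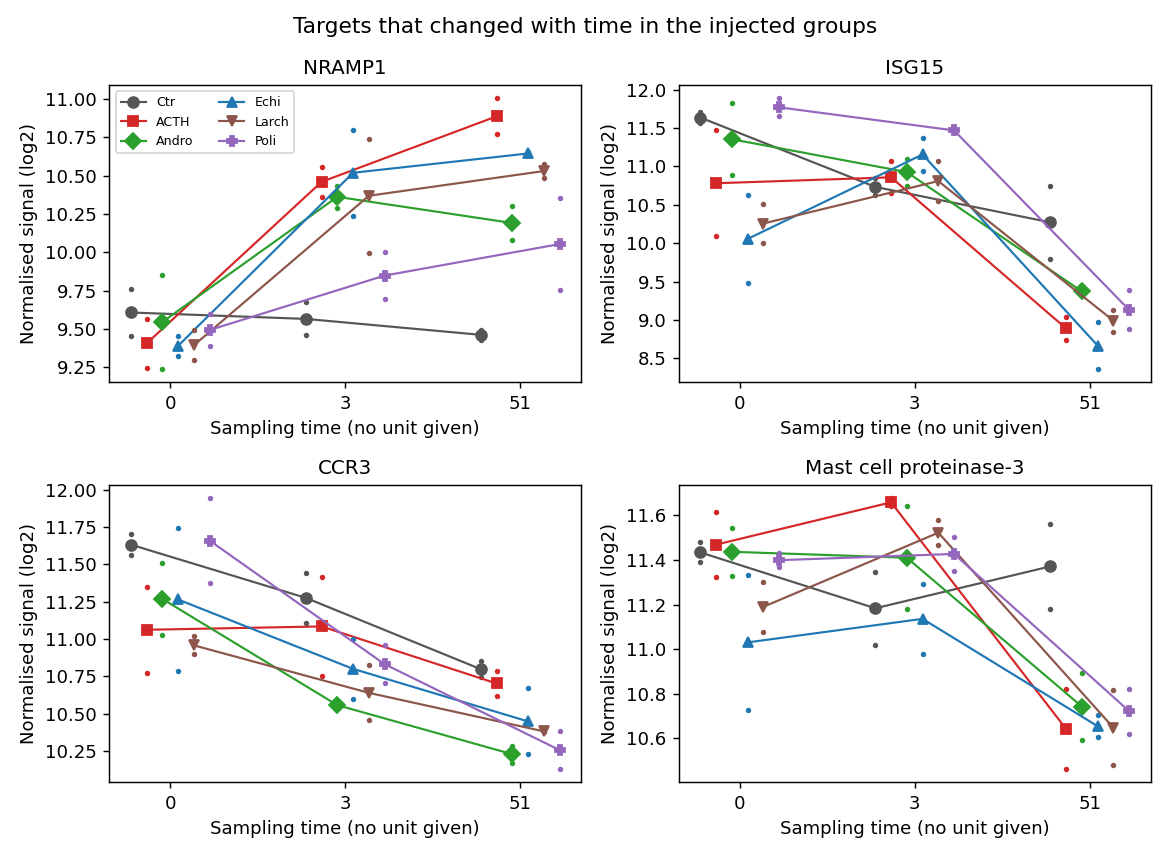
Normalised log2 signal of NRAMP1, ISG15, CCR3 and mast cell proteinase-3 (vertical axes) at times 0, 3 and 51 (horizontal axes, no unit in the labels) in 6 groups; large symbols joined by lines are pool means and small points are the 2 arrays of each pool. NRAMP1 was higher at 51 than at 0 by 1.48 in ACTH and 0.56 in Poli, with -0.15 in Ctr, and ISG15 changed by -1.36 in Ctr.

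Transcripts of antigen presentation lay lower at 51. The list median over its 33 members was -0.50, 32 of them were negative, and camera called the list (adjusted p = 4.94e-18). With an estimated correlation the p = 0.0178 and the adjusted p = 0.160, and fry gave an adjusted p = 0.0373. No single member passed over all targets with limma, while 20 fell when adjusted over the list alone. By group the median change was 0.01 in ACTH, -0.14 in Larch, -0.44 in Andro, -0.81 in Echi and -1.12 in Poli, and -0.55 in the uninjected Ctr. The value in ACTH rests on 2 unlike arrays at 0: it was 0.61 without replicate 1 and -0.78 without replicate 2, and -0.11 or 0.04 without replicate 1 or 2 at 51. In Andro it was -0.28 without replicate 2 at 0, in Echi -0.50 without replicate 1 at 0 and -0.30 without replicate 2 at 51, and in Larch -0.06 and -0.08 without replicate 1 at 0 and at 51. Without replicate 1 the list median was -0.34. Without replicate 1 of the ACTH group at 0 alone it was -0.40, with an adjusted p of 4.67e-09 from camera (0.280 with an estimated correlation) and of 0.188 from fry. The 22 MHC class I clones within it had a median of -0.58. Ribosomal proteins had a median of -0.45 over 10 members, all negative in the fit. By group their median change was 0.16 in Larch, -0.14 in Echi, -0.24 in ACTH, -0.89 in Andro and -1.07 in Poli, and -0.53 in Ctr. RPS6 fell by 0.84 ± 0.17 (limma adjusted p = 0.0429), with -1.21 in Ctr, and 4 members fell when adjusted over the list alone. Without the ACTH array named above, RPS6 had -0.86 ± 0.17 and an adjusted p = 0.0765. Camera gave that list an adjusted p = 8.35e-06, but with an estimated correlation the p = 0.0673.

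At 51, 20 targets rose and 56 fell, with 1515 at an unadjusted p under 0.05. The count was 6 without replicate 1, 162 without replicate 2, 13 without Andro, 28 without Echi and 13 without Poli. Without single replicate 1 arrays it was 17 (ACTH at 0), 14 (Echi at 0), 31 (Larch at 0), 49 (Andro at 3), 44 (Poli at 3) and 42 (Larch at 51). Without single replicate 2 arrays it was 172 (ACTH at 0), 147 (Echi at 0), 131 (Larch at 0), 31 (ACTH at 3), 43 (Echi at 3), 39 (Echi at 51) and 35 (Poli at 51). Of the other tested lists, neutrophil markers (median -0.11), monocyte and dendritic markers (0.07), cytokines (0.02), Toll-like receptor signalling (0.09), the glucocorticoid receptor axis (0.06) and adhesion (0.02) had no member past the limma threshold over all targets and no camera call. When adjusted over the list alone, 1 neutrophil marker rose and 3 fell, 2 monocyte markers rose, and 1 Toll-like receptor list member rose. Fry gave an adjusted p = 0.0481 for both the monocyte and the Toll-like receptor list, and 0.0854 for both without replicate 1 of the ACTH group at 0, so these calls ended.

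Lists with too few measured members for a test gave single values. The glucocorticoid-induced list kept ZFP36 (-0.05 at 3 and -0.01 at 51) and ADORA3 (-0.19 and -0.34, adjusted p at 51 = 0.122). In the erythroid list HBB, the beta globin gene, had a value of -1.54 ± 0.44 at 51 (adjusted p = 0.140). Among the 4 interferon response members, ISG15 alone passed; IRF1 had -0.24 and MX2 -0.29 at 51. No member of the B cell (4 kept), natural killer (1), platelet (3), antioxidant (1), circadian clock (4), immediate early (4), apoptosis (4), cell cycle (1) or oxidative phosphorylation (2) list passed the limma threshold at 3 or 51. The heat shock list had 0 members left by the filter.

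The third comparison asked whether the change in the injected groups exceeded that in the uninjected control, the contrast that sets ACTH apart from time. NRAMP1 differed by 0.91 ± 0.32 at 3 (adjusted p = 0.930) and by 1.16 ± 0.32 at 51 (adjusted p = 0.9999), and neither value passed. The signal processing protein had 0.74 ± 0.22 and 0.79 ± 0.22. Other described targets with small p values were Hoxa-7 (-0.77 at 3 and -0.74 at 51), fetuin (-0.79), potassium-chloride cotransporter-1 (-0.70), the protease inhibitor SLPI (-0.75) and the branched-chain aminotransferase BCAT1 (-0.77). The antigen presentation list had a median difference of 0.19 at 51 (camera adjusted p = 0.0703; estimated correlation p = 0.401), and no list was called at either time with camera or fry. When replicate 1 of the ACTH group at 0 was left out, camera called the antigen presentation list at 51 (median 0.28, adjusted p = 0.0279); with an estimated correlation (unadjusted p = 0.392) and with fry (adjusted p = 0.809) it was not called. Limma called 0 targets at 3, with 382 at an unadjusted p under 0.05, and 0 at 51, with 217. The count at 51 was 1 without replicate 2 of Ctr at 51 or without replicate 1 of Poli at 51. The control had 1 pool per time, and the median standard error was 0.268, against 0.110 for the change within the injected groups. None of the time changes given here was therefore separated from time of sampling by a test.

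The remaining main comparisons asked how each plant product group differed from the ACTH group on the basal diet, over 3 times. The 3 pools of a group came from the same sheep at 3 times, so these tests do not measure variation between sheep. A difference here covers diet and sheep, with their genotypes, together. All calls of single targets in these 4 comparisons ended when replicate 1 of the ACTH group at 0 was left out, as set out with the counts below. In Andro, transcripts of antigen presentation were lower: the MHC class I clone EF489531 by -2.10 ± 0.28 (adjusted p = 0.00113, n = 3 pools per group), the class I gene E9 by -2.02 ± 0.35, the F9 gene by -1.90 and the B564 gene by -1.84. The class II genes DRB1 (DQ659127, -1.59 ± 0.19) and DRA (-0.86), which build the peptide receptor for helper T cells, were lower too. DQA2, another class II gene, was higher by 1.23 ± 0.16 (adjusted p = 0.00113), with differences of 1.01, 1.31 and 1.37 at 0, 3 and 51. Elongation factor-1 alpha was lower by -2.04 ± 0.28, RPLP0 by -1.35 and RPL4 by -1.42. Higher in Andro were a KRAB repressor clone (1.07), serum albumin (0.97), the glutamate transporter EAAT3 (0.93 ± 0.22, adjusted p = 0.0264) and thyroxine-binding globulin (0.74).

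In Echi the class I clone EF489531 differed by -2.10 ± 0.28 and E9 by -1.99, and the class I 3' end sequence M34674 by -1.82. The immunoglobulin light chain variable clones AF172703 and AF172689 were each lower by -1.92. EAAT3 was higher by 1.19 ± 0.22 (adjusted p = 0.00681), as were the melanocortin receptor MC1R (0.82), alpha A crystallin (0.80), the neuropeptide Y1 receptor (0.80) and the T cell growth factor IL2 (0.75). In Larch, EF489531 (-2.09 ± 0.28), E9 (-1.88), elongation factor-1 alpha (-1.83), B564 (-1.78) and annexin 2 (-1.54 ± 0.27) were lower, and no described target was higher. In Poli, E9 (-2.03), EF489531 (-1.94), the lambda-1e light chain variable region (-1.94 ± 0.26), elongation factor-1 alpha (-1.88) and light chain clone AF172689 (-1.83) were lower. Higher in Poli were the KRAB repressor clone (1.16), the glycoprotein hormone alpha subunit (0.81), thyroxine-binding globulin (0.74), the angiopoietin receptor tie-2 (0.74) and the drug transporter ABCG2 (0.73).

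As a list, antigen presentation was lower in each of these comparisons. Its median was -0.80 in Andro, -1.14 in Echi, -0.99 in Larch and -1.01 in Poli, with 16, 22, 17 and 20 of 33 members lower over all targets, and 1 higher (DQA2) in Andro. When adjusted over the list alone, 23, 25, 23 and 23 were lower, and 2, 1, 1 and 0 higher. Camera gave adjusted p values of 8.05e-12, 5.31e-16, 2.69e-17 and 1.36e-15. With an estimated correlation the p values were 0.0442, 0.0234, 0.0196 and 0.0248, and the adjusted p values 0.279, 0.211, 0.177 and 0.223, so no call held; fry called all 4, with adjusted p values from 0.00273 to 0.0133. Without replicate 1 of the ACTH group at 0 the medians were -0.48, -0.84, -0.75 and -0.74, camera gave adjusted p values from 1.09e-11 to 8.09e-07 (0.207 to 0.252 with an estimated correlation), and fry called the list in Echi alone (0.0460; the others from 0.0803 to 0.186). Without replicate 1 of every pool the medians were -0.50, -1.11, -0.70 and -0.67, and without replicate 2 they were -1.13, -1.25, -1.38 and -1.34. By time the medians were -0.44, -0.61, -0.85 and -0.31 at 0, -0.89, -1.12, -0.97 and -1.19 at 3, and -0.87, -1.35, -0.74 and -1.17 at 51. At 0, replicate 1 of the ACTH group lay above these 4 pools by 1.11 to 1.53. Its duplicate differed from them by 0.003, 0.0007, 0.10 and -0.22, so the difference at 0 rested on 1 array. The same list had a median of 0.40 in ACTH against Ctr, and of -0.38, -0.54, -0.34 and -0.41 in Andro, Echi, Larch and Poli against Ctr.

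**Figure D2:**
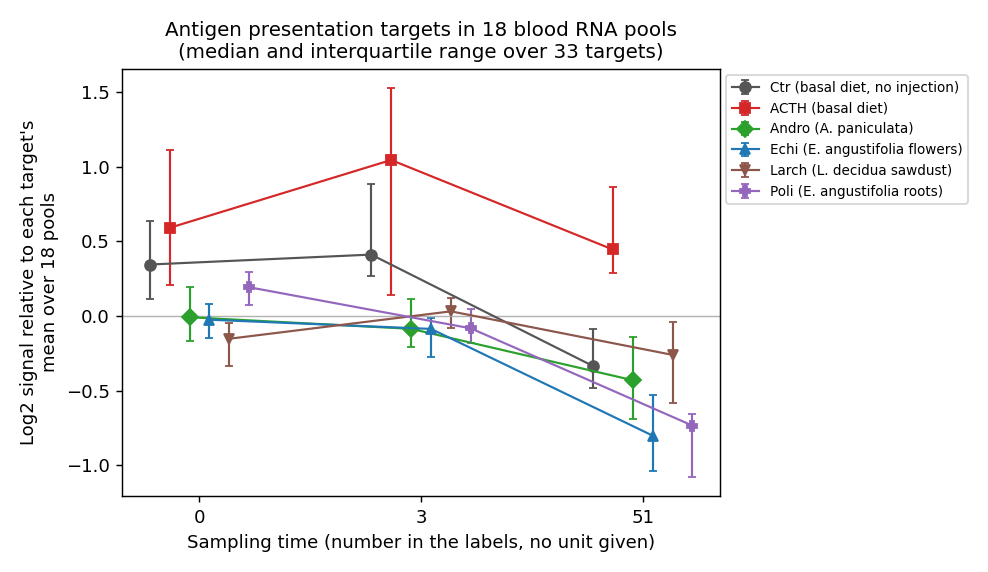
Median log2 signal of the 33 antigen presentation targets in each of 18 pools, relative to each target's mean over pools (vertical axis), at times 0, 3 and 51 (horizontal axis, no unit in the labels); bars span the interquartile range over targets. The ACTH group lies highest at each time, and the plant product groups differed from it over 3 times by -0.80 to -1.14. At 0 its replicate 1 lay above Ctr by 0.76 and its replicate 2 lay at -0.35 from Ctr.

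Ribosomal proteins, the core of the translation machinery, were lower as a list, with medians of -0.50 in Andro, -0.89 in Echi, -0.48 in Larch and -0.63 in Poli. Of 10 members, 3, 6, 2 and 3 were lower over all targets and 4, 8, 5 and 5 when adjusted over the list alone. RPL4 was lower in all 4 comparisons (-1.42, -1.26, -1.02 and -1.24) and so was RPS12 (between -0.97 and -1.29). Camera gave adjusted p values of 0.000286, 7.48e-06, 0.000601 and 5.36e-05, but with an estimated correlation the p values were 0.114, 0.0662, 0.129 and 0.0879. Fry called the list in Andro (adjusted p = 0.0349), Echi (0.0132) and Poli (0.0303). When replicate 1 of the ACTH group at 0 was left out the medians were -0.49, -0.80, -0.47 and -0.65, camera called all 4 (adjusted p from 4.65e-06 to 0.000160) but none with an estimated correlation (0.207 to 0.252), and fry called Echi alone (0.0429; Andro 0.0905, Poli 0.0803). In Larch the median was -0.23 without time 0 and -0.78 without time 51. The list had a median of 0.44 in ACTH against Ctr.

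Single members of other lists also differed. IRF1, a transcription factor of the interferon response, differed by -1.17 ± 0.13, -0.65, -1.04 and -1.14 in Andro, Echi, Larch and Poli. CTSD, the lysosomal protease cathepsin D on the monocyte list, differed by -1.27 ± 0.28, -1.21, -1.27 and -1.21, and CD247, the zeta chain of the T cell receptor complex, by -0.72 ± 0.14, -0.65, -0.56 and -0.51. Among 81 immunoglobulin variable region clones, a family grouped by description and not a fixed list, 37, 40, 18 and 37 were lower and 0, 1, 0 and 0 higher. In the T cell list 6, 6, 1 and 3 of 61 members were lower and 0, 3, 0 and 0 higher; when adjusted over the list alone 7, 6, 3 and 0 were lower and 1, 3, 0 and 0 higher. Medians of that list lay between -0.04 and 0.01.

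Single cytokine and stress axis genes were higher. IL2 (0.70) and IL10 (0.40) passed in Andro, IL2, IL5 (0.49) and the neutrophil chemokine CXCL8 (0.51) in Echi, and IL10 (0.45) in Poli; over the cytokine list alone 2, 4, 0 and 1 of 19 were higher. On the glucocorticoid receptor axis, HSD11B1, the enzyme that regenerates cortisol from cortisone, was higher in Andro (0.69) and Poli (0.68). The mineralocorticoid receptor NR3C2 (0.74), MC1R and the corticotropin-releasing hormone receptor CRHR1 (0.45) were higher in Echi. The counts for this list when adjusted over the list alone were 1, 3, 0 and 1 higher. In Echi the neutrophil genes ITGB2 (-0.68) and CYBB (-0.84 and -0.89 for its 2 targets) were lower and the cathelicidin CATHL1 (0.58) higher, which were also the members past the threshold when adjusted over the list alone. Over the neutrophil list alone 0, 0 and 0 passed higher and 0, 2 and 0 lower in Andro, Larch and Poli. CD80 (0.54), the death receptor FAS (0.65), E-selectin (SELE, 0.44) and carbonic anhydrase CA1 (0.50) were higher in Echi, and TLR10 (-0.50) and IGHA1 (-0.77) lower. JUND was lower in Andro (-0.87) and Poli (-0.85). MYC (-0.46) and ZFP36 (-0.45) were lower and BCL2 (0.51) higher in Poli. When adjusted over the list alone, 0, 1, 0 and 0 monocyte list members were higher and 2, 1, 1 and 1 lower, 1, 1, 0 and 0 Toll-like receptor list members higher and 1, 1, 0 and 0 lower, and in the adhesion list SELE passed as higher and ITGB2 as lower in Echi. With all arrays, camera called none of the cytokine, neutrophil, monocyte, T cell, Toll-like receptor, glucocorticoid axis or adhesion lists in these 4 comparisons. Fry tests the members of a list on their own, where camera sets them against the other targets. With fry, the neutrophil list was called as lower (adjusted p from 0.0158 to 0.0369) and the glucocorticoid axis list as higher (from 0.00668 to 0.0484) in all 4. Fry also called the monocyte list as lower in Andro (0.0349), the cytokine list as higher in Echi (0.0158) and the adhesion list as higher in Poli (0.0484). When replicate 1 of the ACTH group at 0 was left out, fry called the neutrophil list (0.0461), the glucocorticoid axis list (0.0307) and the cytokine list (0.0461) in Echi alone. Its other calls ended: the neutrophil list had 0.0905, 0.159 and 0.0803 in Andro, Larch and Poli, the glucocorticoid axis list 0.0905, 0.159 and 0.151, the monocyte list in Andro 0.0905 and the adhesion list in Poli 0.214. Camera then called the neutrophil (0.0274) and glucocorticoid axis (0.0475) lists in Larch, but neither with an estimated correlation (0.225 for both).

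Over all 9714 targets limma called 252 higher and 548 lower in Andro, 515 and 719 in Echi, 18 and 243 in Larch, and 340 and 561 in Poli. Counts at an unadjusted p under 0.05 were 2557, 3099, 1755 and 2717. Without replicate 1 of the ACTH group at 0 limma called 0 targets in each of the 4 comparisons, with 1670, 2457, 831 and 1675 at an unadjusted p under 0.05. Every target called with it kept its sign, at 0.735 (Larch) to 0.884 (Echi) of its size (medians), and the median standard error was 0.149, against 0.141. Thus EF489531 had -1.63 ± 0.45 in Andro (adjusted p = 0.163), against -2.10 ± 0.28 with all arrays. Without the duplicate of that array the counts were 1542, 2003, 852 and 1887. Without time 3 the counts were 0, 1, 3 and 0, and without replicate 1 of every pool 0, 77, 0 and 0. Every called target kept its sign in both cases. Fits with arrays left out share data with the fit that chose the targets, so kept signs are no independent support. Without time 3 the size of the called differences was 0.886, 0.965, 0.872 and 0.881 of that over all pools (medians), and without replicate 1 it was 0.722, 1.11, 0.697 and 0.766. Without 2 arrays of Echi that correlated poorly with their duplicates or with the authors' values, an alternative added after the data were seen, the Echi count was 371. Leaving out time 51 gave 304 in Andro, 519 in Echi and 275 in Poli, leaving out time 0 gave 537 in Echi and 103 in Larch, and leaving out replicate 2 gave 349 in Echi and 626 in Larch. Of the other single arrays, Andro had 424 without replicate 1 of Echi at 51 and 446 without replicate 2 of Poli at 51. Echi had 551, 640 and 754 without its replicate 2 at 0, 3 and 51, 2042 without its replicate 1 at 3, 817 without replicate 1 of Larch at 51 and 820 without replicate 2 of Poli at 51. Larch had 439 without its replicate 2 at 51. Poli had 434 without replicate 1 of Echi at 51, 481 without its replicate 2 at 3 and 596 without replicate 2 of Echi at 3.

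With all arrays, the ACTH group differed from each other group in more targets than any 2 other groups did. Against Ctr over 3 times, the ACTH pools were higher in elongation factor-1 alpha (1.71 ± 0.28), annexin 2 (1.61), DRB1 (EF380349, 1.38 ± 0.21, adjusted p = 0.00772), the glucose transporter GLUT-3 (1.10), RPL4 (1.06), GAPDH (0.98), vimentin (0.80), IRF1 (0.77) and NRAMP1 (0.71), and lower in CD3E (-0.53) and aldolase B (-0.68). In all, 179 targets were higher and 19 lower in ACTH than in Ctr. With replicate 1 of the ACTH group at 0 left out, 0 targets passed with limma between ACTH and Ctr (585 at an unadjusted p under 0.05), and the antigen presentation median was 0.27, against 0.40. The ACTH arrays correlated with arrays of other groups at a mean of 0.903 and the remaining arrays at 0.929, and the 2 ranges overlapped. Limma called 0 targets between Andro and Ctr (910 at an unadjusted p under 0.05), 3 between Echi and Ctr, 0 between Larch and Ctr (495), and 2 between Poli and Ctr. Each group was its own set of sheep, so a difference between groups covers diet and sheep together. These group comparisons were added after the diet results were seen.

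**Figure D3:**
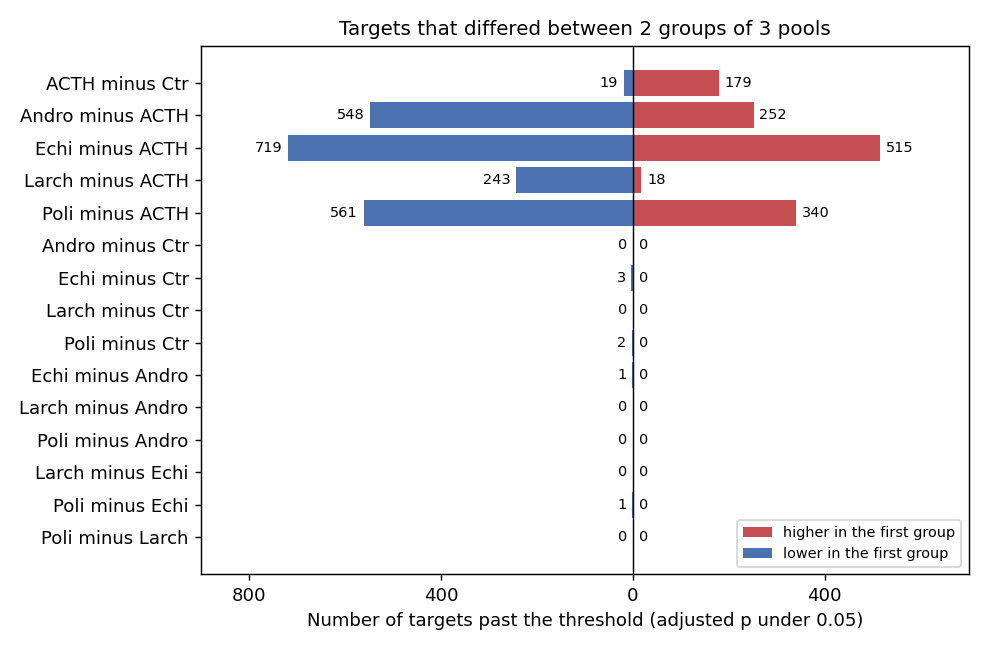
Number of targets past the limma threshold (horizontal axis) between pairs of groups of 3 pools each, higher to the right and lower to the left. Comparisons with the ACTH group gave 198 to 1234 targets, and all others gave 0 to 3; without replicate 1 of the ACTH group at 0 the former gave 0 (585 to 2457 at an unadjusted p under 0.05) and the latter 0 to 3.

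The ACTH and Ctr pools were also compared at each time, against the spread between duplicate arrays only, with 1 pool on each side. At 0 limma called 0 targets (554 at an unadjusted p under 0.05). At 3 the ACTH pool was higher in the light chain variable clone AF172683 (2.49 ± 0.39, n = 2 arrays per pool), the class I genes E9 (2.47) and B564 (2.25), elongation factor-1 alpha (2.16) and annexin 2 (2.12). It was lower in EAAT3 (-1.57 ± 0.18, limma adjusted p = 8.58e-06), alpha A crystallin (-1.38), aldolase B (-1.20), CATHL1 (-0.99) and the clock gene PER3 (-0.97). At 51 the ACTH pool was higher in DRB1 (2.25 ± 0.40, limma adjusted p = 0.00265), annexin 2 (1.99), GLUT-3 (1.95), the class I clone EF489531 (1.92) and RPLP0 (1.73). It was lower in EAAT3 (-0.94), CLN5 (-0.87), musclin (-0.75) and SLPI (-0.71). With probe set 1 alone the CLN5 difference was reversed. At 3, 400 targets were higher and 235 lower, and at 51, 133 and 21. With replicate 1 of the ACTH group at 0 left out, the counts were 1 at 0, 848 at 3 and 275 at 51. The count at 0 was 523 without its duplicate. At 3 it was 97 and 319 without replicates 1 and 2 of ACTH, and 181 and 286 without replicates 1 and 2 of Ctr. At 51 it was 55 and 25 without replicates 1 and 2 of ACTH, and 26 without replicate 1 of Ctr. These tests compare RNA pools and carry no information on variation between sheep.

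The change from 0 in each plant product pool was set against the change in the ACTH pools in the same way. At 3 the change differed for 9 targets in Andro, 1 in Echi, 25 in Larch and 1 in Poli, and at 51 for 14, 13, 0 and 6, with 642 at an unadjusted p under 0.05 beside the 0 from limma in Larch. With that ACTH array left out the counts were 248, 294, 391 and 253 at 3, and 48, 60, 33 and 136 at 51. Without its duplicate the counts at 51 were 170, 176, 131 and 137, and the count in Echi at 51 was 278 without replicate 1 of Echi at 51. Leaving out each array of the pools compared gave 1 to 248 in Andro, 0 to 294 in Echi, 0 to 391 in Larch and 0 to 253 in Poli at 3, and 1 to 170, 0 to 278, 0 to 131 and 0 to 137 at 51. None of these targets carries a gene description. All tests rest on 2 arrays per pool, with a median standard error of 0.328.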

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

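The comparison with the uninjected pools, cyclic loess, the test of a wrong label, leaving out 1 ACTH array and the full set of splits that part every group were chosen only after the results were seen; the other tests here were set before. Over 30 sets of 5 injected groups, 2 values lay far from the rest, where chance gives about 1 in 20. The signal processing protein changed from 0 to 3 by 0.87 in the ACTH group, against 0.42 to 0.50 in the other 4 injected groups. Alpha-1 antitrypsin changed from 0 to 51 by 1.14 in Echi, against 0.31 to 0.45. The test of the difference in change from 0 to 3 against the ACTH pools passed for 9 targets in Andro, 1 in Echi, 25 in Larch and 1 in Poli. From 0 to 51 it passed for 14 in Andro, 13 in Echi and 6 in Poli. Without replicate 1 of the ACTH group at 0 these counts were 248, 294, 391 and 253 at 3, and 48 in Andro, 60 in Echi and 136 in Poli at 51. Leaving out each array of the pools compared gave 1 to 248 in Andro, 0 to 294 in Echi, 0 to 391 in Larch and 0 to 253 in Poli at 3, and 1 to 170 in Andro, 0 to 278 in Echi and 0 to 137 in Poli at 51.

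Antigen presentation transcripts were lower in the 4 plant product groups than in the ACTH group, by a mean of -0.98 over the list medians. With all arrays, the list median stood at percentile 0 of random lists matched on signal in all 4 comparisons. This argues against an effect of signal level alone. It cannot exclude an array effect on these members together, since 22 of the 33 are MHC class I clones and the estimated correlation between members was 0.341. The 4 comparisons also share the ACTH pools, and the percentiles were not repeated without replicate 1 of the ACTH group at 0. Cyclic loess gave -1.09, which argues against a bias left by quantile normalisation. The probe set with the smaller size gave -0.87, which argues against a faulty oligo per target. All calls of single targets rest on replicate 1 of the ACTH group at 0: without it limma called 0 in each comparison (831 to 2457 at an unadjusted p under 0.05). The list medians moved from a range of -1.14 to -0.80 to one of -0.84 to -0.48, and the median standard error from 0.141 to 0.149. Some calls ended with little change in size, such as EAAT3 in Echi (1.19 with the array and 1.16 without it). Why the calls ended was not tested. A wrong label of replicate 1 of the ACTH group at 0 stays open. It correlated at 0.979 with replicate 2 of the ACTH group at 3 and at 0.902 with its duplicate. A best match among 34 arrays is favoured over 1 duplicate, and 31 of 36 arrays had one, so no test here decides it. In the authors' matrix its column for probe set 2 matched this array at 0.692 and matched best Ctr at 0 (0.699). Its column for probe set 1 matched this array at 0.998. The ACTH group also lay above the uninjected one (by 0.40, or 0.27 without the array). The sheep of the ACTH pools may therefore differ too, for example in MHC haplotype. No haplotype was used here, and the design does not separate sheep from diets. Of the 10 splits of 6 pools into 3 and 3, the real one alone, 1 split, gave as many targets in each comparison (800 in Andro, 1234 in Echi, 261 in Larch and 901 in Poli; highest other split 0), and 10 splits are too few for a share under 0.05.

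The same list was lower at 51 than at 0 in the injected groups, with a median of -0.50. Its percentile of 0 among matched random lists argues against an effect of signal level alone. An array effect on these members together is not excluded, as most are MHC class I clones. A change shared with the uninjected sheep stays open: their median change was -0.55, inside the range of the injected groups from -1.12 to 0.01 (ACTH, at the upper end, had 0.61 without its replicate 1 at 0 and -0.78 without replicate 2), and with 1 uninjected pool per time it cannot be told apart from an effect of ACTH. For the count of targets at 51, 3 of 100 splits of the 10 pools gave as many as the real 76, a share under 0.05, but most of these splits ignore that the pools pair by group, and the highest other split gave 212, which points to a structure of the pools other than time. Of the 16 splits that part every group, the real one was the 1 with as many (highest other 0), and 16 splits are too few for a share under 0.05, so chance is not settled.

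NRAMP1 was higher at 3 and at 51 than at 0 in the injected groups. A single faulty oligo is argued against, because the smallest of the changes over both oligos and both times was 0.55, and the oligos gave 1.11 and 0.62 at 3 and 1.48 and 0.55 at 51. An effect of ACTH may account for it, as the value in the uninjected group was -0.04 at 3 and -0.15 at 51, but the difference between them did not pass its test and time of sampling stays open. For the count of targets at 3, 2 of 100 splits of the pools gave as many as the real 10, and the highest other split gave 101, several times the real count, which points to a structure of the pools other than time. That split parts every group as the real one does, and 2 of the 16 such splits gave as many, so chance is not excluded among them.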

How the results depend on the processing

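The mean pixel column, cyclic loess, leaving out 2 doubted Echi arrays or 1 doubted ACTH array, and leaving out each array in turn in the pool fit were chosen only after the data were seen. Over all alternatives, 636 values of the 47 results named from the pool fit, each 1 gene in 1 comparison, kept direction and side of the threshold. Some genes recur in several comparisons. Another 270 kept direction and lost the call, and 1 reversed. For the 19 such results from single pools these were 207, 89 and 1. Only 1 of the 47 and 1 of the 19 kept its call throughout. In the pool fit most calls were lost without the doubted ACTH array (43 of 47), without replicate 1 (41 of 47) and without time 3 (35 of 35). The reversed values were the T19 clone at 51 (0.0596) and CLN5 in ACTH against Ctr at 51 (0.0677), both with probe set 1. No list call was kept throughout. Of the 11 list calls from camera, each 1 list in 1 comparison, 0 held with an estimated correlation, while fry gave 21 such calls. Leaving out a group, time or hybridization lowered some counts and raised others. Fewer targets were tested with the upper part by signal; elsewhere the cause was not tested. A slide or scan block was not run, as the labels give none. Signal limits the data further: the negative controls reached an intensity of 267 to 1040 at their 95th percentile, against array medians of 804 to 2060, and the oligos of a target correlated in change at 0.12 to 0.39. In level, over targets within an array and without the filter, the oligos correlated at 0.24 to 0.36.

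Counts that moved by over 1.5 times follow by setting; those at 3 or 51 for a plant product are differences in change from the ACTH pools. With 75th percentile scaling the change from 0 to 3 gave 5 targets, Andro 439, Larch 125, Poli 389, ACTH against Ctr at 3 410, Andro at 3 4, Echi at 3 0, Andro at 51 3, Echi at 51 3, Larch at 51 13 and Poli at 51 1. Normexp background correction gave Poli at 51 11. No filter gave 50 for the change from 0 to 51 and 7 for Echi at 51. Keeping the upper part of targets by signal gave Echi 763, Larch 149, ACTH against Ctr at 3 353, Andro at 3 0, Larch at 3 2, Poli at 3 0, Andro at 51 0 and Echi at 51 6. Probe set 1 gave 6 for 0 to 3, 25 for 0 to 51, 1 for injected against control at 51, Andro 483, Echi at 3 0, Larch at 3 2, Poli at 3 0 and Andro at 51 4. Probe set 2 gave 5 for 0 to 3, 16 for 0 to 51, Andro 518, Andro at 3 20, Echi at 3 0, Larch at 3 9 and Poli at 51 10. The authors' processed values gave 5 for 0 to 3, 48 for 0 to 51, Andro at 3 41, Echi at 3 225, Larch at 3 233, Poli at 3 41, Echi at 51 72, Larch at 51 27 and Poli at 51 169. They include the column for replicate 1 of the ACTH group at 0 with probe set 2, which matched its own array at 0.692. That pool enters each difference in change from the ACTH pools. The mean pixel column gave Larch at 3 15 and Poli at 3 0. Cyclic loess gave Andro at 3 3, Larch at 3 16, Poli at 3 0, Andro at 51 3, Larch at 51 7 and Poli at 51 2. Without the 2 doubted Echi arrays, Echi had 371, Andro at 3 19, Echi at 3 0, Poli at 3 3, Echi at 51 2, Larch at 51 2 and Poli at 51 47. Without the doubted ACTH array (replicate 1 at 0), 0 to 51 gave 17, Andro 0, Echi 0, Larch 0, Poli 0, ACTH against Ctr 1 at 0 and 275 at 51, Andro at 3 248, Echi at 3 294, Larch at 3 391, Poli at 3 253, Andro at 51 48, Echi at 51 60, Larch at 51 33 and Poli at 51 136. With the pool as a random block over 36 arrays, the counts were 32 for 0 to 3, 284 for 0 to 51, 2 for injected against control at 51, Echi 1880, Larch 477 and Poli 1367. The correlation between the 2 arrays of a pool in that fit was 0.0511, so it takes duplicate arrays as nearly separate samples. Adding the replicate number as a block gave 33, 275 and 2, and Andro 1238, Echi 1926, Larch 485 and Poli 1377; at array level this block gave Echi at 3 0.

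Leaving out 1 replicate number over all pools, 1 group or 1 time gave 1 to 7 targets for 0 to 3, 6 to 162 for 0 to 51, 0 for injected against control at 3 and 0 to 1 at 51, 0 to 989 in Andro, 1 to 537 in Echi, 0 to 626 in Larch and 0 to 1263 in Poli. Leaving out each of the 36 arrays in turn gave 4 to 13 for 0 to 3, 14 to 172 for 0 to 51, the same 2 ranges against control, 0 to 1542 in Andro, 0 to 2042 in Echi, 0 to 852 in Larch and 0 to 1887 in Poli. For single pools, where the lone array was assumed to vary like the others, ACTH against Ctr gave 0 to 523 at 0, 97 to 319 at 3 and 25 to 110 at 51. Andro gave 1 to 248 at 3 and 1 to 170 at 51, Echi 0 to 294 and 0 to 278, Larch 0 to 391 and 0 to 131, and Poli 0 to 253 and 0 to 137.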

Other observations

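The test on mast cell and basophil transcripts was chosen only after the changes at 51 were seen. Single receptor genes of T cells differed between groups. Among 7 targets of T19, a receptor family of gamma delta T cells, 3 were lower in Andro and 2 in Echi than in ACTH, and T19 (S76323) differed by -0.64 and -0.66. Of 26 T cell receptor delta clones, 2 were higher in Echi and none passed with limma in Andro, Larch or Poli, where the medians were 0.06, 0.01 and 0.06. Of 17 T cell receptor beta clones, 2 were lower in Andro, 3 lower and 1 higher in Echi, and 2 lower in Poli, with 0 from limma in Larch (median -0.10). OTCR9 was lower in Andro (-0.64), Echi (-0.70) and Poli (-0.62), OTCR10 in Andro (-0.53) and Poli (-0.42), and OTCR25 (-0.66) and OTCR6 (-0.60) in Echi, where OTCR5 was higher (0.59). These calls and the counts below with the ACTH group were all lost without replicate 1 of that group at 0, where limma called 0 in each comparison.

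In the comparisons with the ACTH group, 210 targets were lower and 9 higher in all 4 plant product groups, among the lower ones RPL4, RPS12, IRF1, CTSD, CD247 and DRB1. Independent calls would give 0.0586 and 0.000866. The comparisons share the ACTH pools, which alone gives a mean correlation of 0.501 between their differences in simulated data with no effect. The observed mean was 0.853. The simulation gave every pool independent noise and held no deviant array. It therefore cannot tell a group difference from a deviant ACTH array, which enters all 4 comparisons. The correlation was not recomputed without replicate 1 of the ACTH group at 0. The ACTH group differed from the mean of the other 5 groups in 1326 targets, and no other group did in more than 2; without replicate 1 of the ACTH group at 0 it was 0 with limma (1972 at an unadjusted p under 0.05). Between 2 plant product groups limma called 0 or 1 target, with 158 to 1647 at an unadjusted p under 0.05.

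CCR3 and mast cell proteinases 1 and 3 fell from 0 to 51, and a lower number of basophils or mast cell precursors in the blood may account for it. Within the injected groups their other transcripts on the array do not bear this out. The median change of 4 other targets was 0.0368, at percentile 59.3 of random lists matched on signal. The IgE receptor beta chain had 0.08, the gamma chain, which monocytes and neutrophils also express, -0.06, mast cell protease-2 -0.01 and tryptase-1 0.09. The median over all 7 targets was -0.06. Against the change in Ctr, tryptase-1 had -0.42, mast cell protease-2 -0.29, the IgE receptor beta chain -0.20 and the gamma chain 0.23. Mast cell proteinases 3 and 1 had -0.56 and -0.50 against Ctr, and CCR3 had -0.005. None of these differences passed with limma, so relative to Ctr the explanation stays open. Eosinophils, which also carry CCR3, were not tested.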
